A study of Arabidopsis thaliana with 2 samples.

How the data were processed

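The data were 2 Affymetrix oligonucleotide arrays of 8297 probe sets each, one hybridised with labelled RNA from whole seedlings of an Arabidopsis thaliana insertion mutant called sks (snakeskin) and one with RNA from wild-type Col-0 seedlings. Per the labels' protocols, total RNA was prepared with a column kit and Trizol, reverse-transcribed from an oligo-dT primer carrying a T7 promoter, and transcribed in vitro into biotin-labelled cRNA. The deposited values are linear signal intensities, 1 per probe set and array. The software and method that summarised the probes into these intensities are not given in the sources used here. The 2%-trimmed mean over all probe sets was 100.2 on both arrays, and the trimmed means differed by less than the 1% limit set in advance for treating the deposited intensities as already scaled. They were therefore used without further scaling. No detection call and no probe-level values were used here. Per the labels, the mean scanner background was 61.92 on the mutant array and 57.92 on the wild-type array, and the mean noise was 1.56 and 1.52.

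Each genotype was represented by 1 array. No test, p-value or standard error between genotypes was computed, and every difference below compares these 2 RNA samples. Signals below 1 were set to 1, log2 was taken, and the wild-type value was subtracted from the mutant value. The 50 control probe sets were left out. Of the other 8247 probe sets, the 4124 whose mean log2 signal over both arrays reached the median (a signal of 19.4) are called measured, and probe sets with at least a 2-fold difference were counted among these. The design, the gene lists, the rule for named genes and most of the other settings tried were written before the data were examined.

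Gene names came from the platform annotation supplied with the series, which can be old. It listed 3864 probe sets, of which 3794 had 1 gene and 70 had several; 4383 non-control probe sets were unnamed here. Symbols were updated through the Entrez gene ID with the RefSeq gene table of TAIR10.1, where 3784 probe sets matched; the remaining 10 kept the annotation's name. Because the files name no genome build, coordinates are not given and the table was used for names, for the order of genes and for the distance between neighbours within the table. Probe sets with several genes were not named. Affymetrix suffixes other than a plain _at (such as _s_at, _f_at, _i_at, _r_at or _g_at) mark probe sets that can share probes or detect related transcripts, so their values may belong in part to a similar gene. Besides genes marked below, such suffixes apply to PSBY, RCA, TUA1, HIS1-3, HIS4, PRL, IAA20, PORB, CML41 and TAPX. They also apply to 1 of the 2 probe sets of ATPMEPCRB and of YLS5.

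The named genes are the 13 probe sets with the highest and the 13 with the lowest log2 difference among measured probe sets of 1 gene, and up to 4 measured members with the largest absolute difference from each of 23 gene lists. For a list, 1 probe set per gene (the brightest) was used. Of 595 list entries, 2 were dropped because the symbol and locus did not match in the gene table, 43 had a single-gene probe set named here, and 36 were measured. Few list members were measured mostly because few had a probe set named here. Names in the lists were compared without regard to capitals or a leading AT. For the 6 lists with at least 3 measured members, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from the 1624 measured genes and matched on mean signal in 20 rank bins. A list outside the middle 95% of the random medians is said to stand apart. This percentile describes these 2 arrays and is not a test across plants.

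As a gauge of background, 23 control probe sets against mouse, yeast and Bacillus sequences were taken as blanks. Their highest signal was 16.8 on the mutant array and 11.1 on the wild-type array. Where the dimmer array of a named probe set was within the blank range, the fold is given as a lower bound, the brighter signal over the highest blank signal of the dimmer array. This rule was set after seeing the data, and the bound depends on it: where the wild type was dimmer, a floor of 16.8 on both arrays gives a lower bound than 11.1 does. Above the blank range lay 52.5% of non-control probe sets in the mutant and 61.7% in the wild type. Each limit rests on 1 blank, and the one at 16.8 in the mutant read 5.4 in the wild type. The blank median was 3.5 in the mutant and 4.4 in the wild type. The 2 shares therefore do not compare how many transcripts were present. Precision is limited by the number of arrays.

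The counting step was tested on simulated arrays of the 4124 measured probe sets with an assumed noise SD of 0.2 log2 units per array. It recovered 85.0% of 200 probe sets changed 2.5-fold and 100% of 200 changed 4-fold, in the right direction. Those changed 1.5-fold passed the 2-fold limit in 5.0% of cases. These shares follow from the assumed noise, which no replicate array could check. They show that the counting step works and give no error rate for the 2-fold differences below. For the list step, 10 of 200 unchanged lists of 7 stood apart. These were drawn from simulated independent values for the 4124 probe sets, whereas the real lists were placed among 1624 genes. Alternatives tried were median centring, quantile normalization, removal of a loess trend (span 0.3), an added offset of 5.1 (the 25th percentile signal), other filters on low values, other fold limits and other choices of probe sets. A floor at the highest blank signal and scaling to the hybridisation spikes were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.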

Results

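RNA from whole seedlings of the sks (snakeskin) insertion mutant and of wild-type Col-0, the background accession of the mutant, was compared on 1 array per genotype. The seedlings were at growth stage 1.0 and had been grown at 22 °C in continuous light on Murashige-Skoog agar with 1% sucrose. The labels do not name the disrupted gene, so the genotype could not be checked against the level of its transcript. Non-control signals had a median of 19.0 in the mutant and 20.3 in the wild type, and the log2 signals of the 2 arrays had a correlation of 0.93 across probe sets, which are not independent replicates.

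The comparison asked which transcripts differ between sks and wild-type seedlings. Transcripts with higher signals in the mutant included THI2.1, which encodes an antimicrobial thionin, the chitinase family gene AT2G43620 and the defensin-like gene AT2G43530. ICL, encoding the isocitrate lyase of the glyoxylate cycle, was 8.75-fold higher. In the wild type, the second thionin gene THI2.2, the GASA family gene AT1G22690 and the cupin family gene AT4G36700 were more abundant. All 7 measured members of the photosynthesis list had lower signals in the mutant, each by less than 2-fold with the deposited scaling, and 6 of 7 after median centring.

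Of 4124 measured probe sets, 335 (8.12%) were at least 2-fold higher and 510 (12.4%) at least 2-fold lower in the mutant, while 3279 lay within 2-fold. At least 8-fold higher were 30 probe sets and at least 8-fold lower 13. These counts were 26 and 7 with both arrays floored at the highest blank signal, and 25 and 5 with the added offset, since some dimmer signals lie in the blank range. The log2 differences had a median of -0.08 and an SD of 0.92 over measured probe sets. With mutant signals lowered to match the 9 hybridisation spike controls, a shift of 0.44 log2 units, 135 probe sets were at least 2-fold higher and 1092 at least 2-fold lower, and 23 and 26 passed 8-fold. The balance of directions thus depended on the scaling. No replicate array shows how much 2 seedling samples of one genotype differ.

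**Figure D1:**
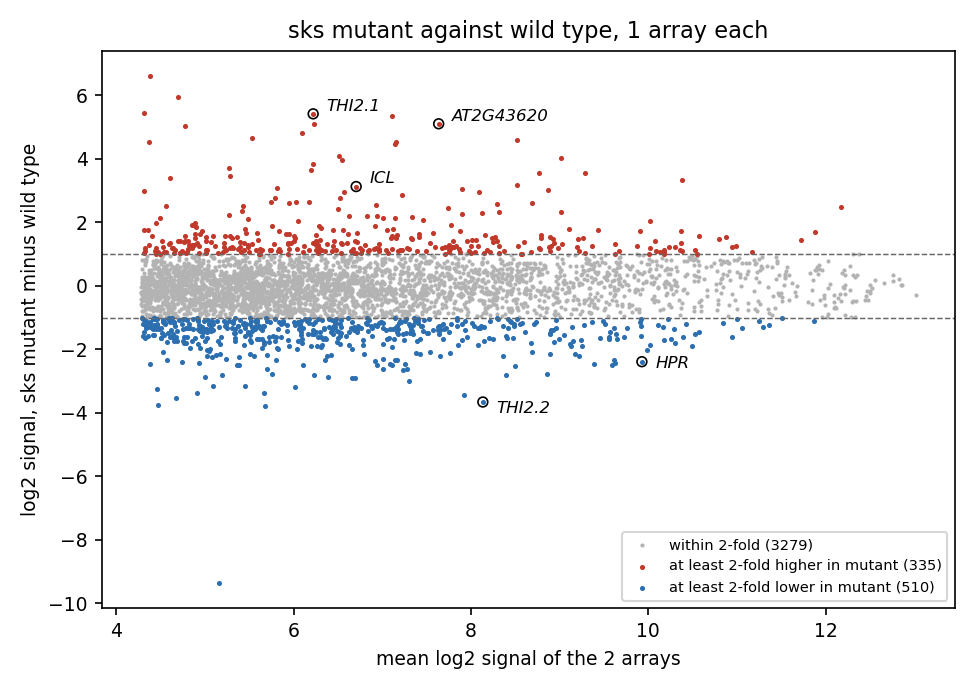
Each point is a measured probe set, with the mean log2 signal of the 2 arrays on the x axis and the log2 signal of the mutant minus that of the wild type on the y axis. Dashed lines mark 2-fold; 335 probe sets lie at or above the upper line and 510 at or below the lower line, and 5 named genes are circled.

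Higher in the mutant, THI2.1 (AT1G72260) had a signal of 487.9 against 11.4, a 42.8-fold difference, with the wild-type signal close to the highest blank of 11.1. A second THI2.1 probe set, with the _s_at suffix, read 156.4 against 4.8, at least 14.1-fold, whereas another with the _i_at suffix read 15.2, within the blank range, against 30.4. AT2G43620 reached 1167.6 in the mutant and 33.9 in the wild type, a 34.4-fold difference. AT2G43530 was 11.9-fold higher, at 2148.5 against 180.9, the brightest mutant signal in this group. AT3G47380, a member of the invertase and pectin methylesterase inhibitor family, was higher on each of its 3 probe sets, at 378.7 against 22.0, 366.8 against 23.7 and 163.4 against 26.1. All 3 carry a shared-probe suffix. AT2G19970, which encodes a protein of the CAP family that includes pathogenesis-related proteins, was at least 12.5-fold higher, with 139.0 in the mutant. The leucine-rich repeat gene AT2G34930 had a signal of 260.8 against 20.6, a 12.7-fold difference. AT1G65500 was 23.2-fold higher (684.5 against 29.5), AT1G27020 14.2-fold (279.9 against 19.7) and AT4G02360 at least 7.14-fold (79.2 in the mutant). These bounds hold for a wild-type blank signal of 11.1. With both arrays floored at 16.8 the log2 difference was 4.86 for the brightest probe set of THI2.1 (5.42 without the floor), 3.22 for its _s_at probe set, 3.05 for AT2G19970 and 2.24 for AT4G02360. AT2G47780, a rubber elongation factor family gene, read 1106.9 against 122.2, a 9.06-fold difference. ICL (AT3G21720) had a signal of 308.7 in the mutant and 35.3 in the wild type.

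Lower in the mutant, THI2.2 (AT5G36910) had a signal of 79.0 against 999.8 in the wild type, a 12.7-fold difference opposite in direction to that of THI2.1. AT1G22690 read 73.8 against 797.6, which is 10.8-fold lower, and AT2G20670 127.4 against 896.5, 7.04-fold lower, on a probe set with the _s_at suffix. In 4 genes the mutant signal was within the blank range, so only bounds are given. AT4G36700 was at least 11.4-fold lower, with 191.0 in the wild type. AT1G65230 was at least 9.76-fold lower, AT4G00780 at least 6.08-fold and AT2G39040, a class III peroxidase gene, at least 4.87-fold. MSRB6 (AT4G04840), a methionine sulfoxide reductase that repairs oxidised methionine, was 6.18-fold lower, at 62.4 against 385.5. The nitrate and peptide transporter family gene AT3G21670 (NPF6.4) was 5.66-fold lower, at 17.5 against 99.1, with the mutant signal close to the highest blank of 16.8. CDI (AT1G64980), annotated as cadmium-induced, was 5.59-fold lower. AT1G15260, AT1G22850 and AT4G38690 were 6.86-fold, 6.13-fold and 5.48-fold lower.

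**Figure D2:**
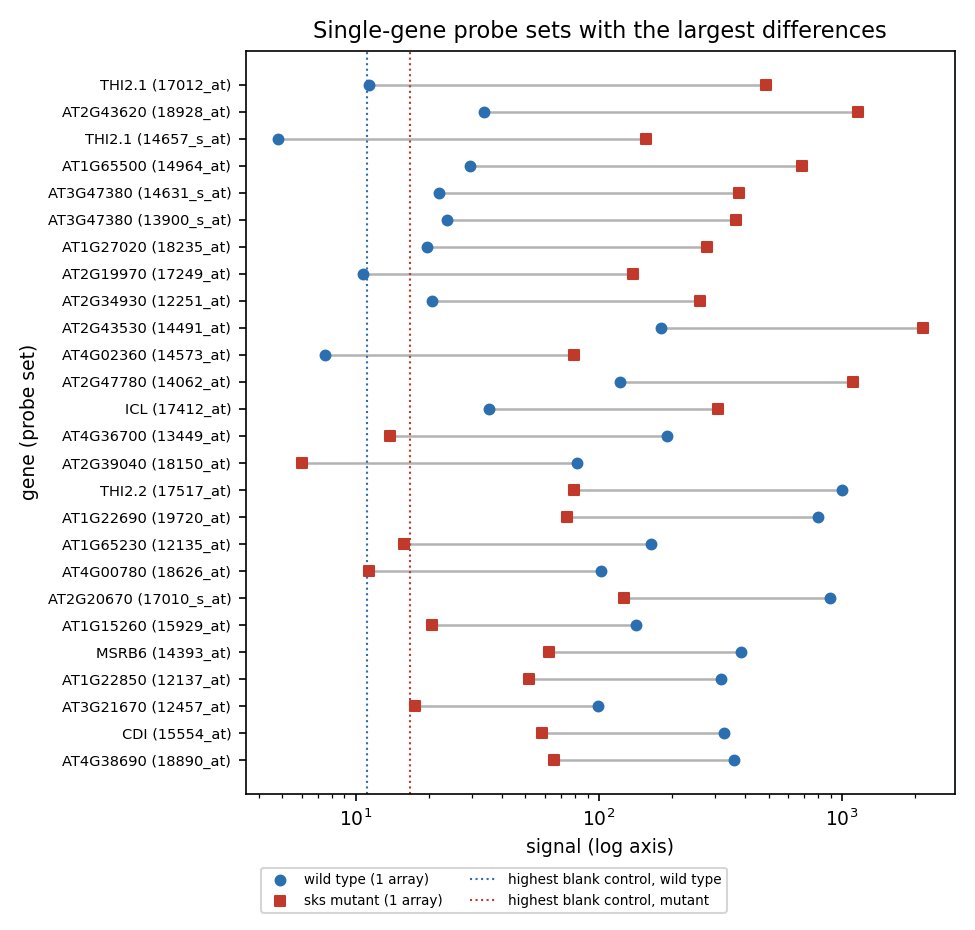
Signals on a log axis of the 13 measured single-gene probe sets with the highest and the 13 with the lowest log2 difference, with the wild type as circles and the mutant as squares, 1 array each. Dotted lines mark the highest blank control signal, 11.1 in the wild type and 16.8 in the mutant; 7 of the 26 dimmer signals lie at or below the line of their array.

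Among the gene lists, the light harvesting and photosynthesis list had 7 measured members out of 48, and all 7 had lower signals in the mutant, except that LHB1B2, at -0.07, lay at 0.02 after median centring. None differed by 2-fold or more with the deposited scaling. The median log2 difference was -0.47, which stood at the 0.99th percentile of matched random lists. PSBY, a small photosystem II protein, had a signal of 2815.6 against 5618.3. PSAN, a photosystem I subunit, read 1848.3 against 2710.7, RCA, the Rubisco activase, 4224.3 against 5970.1, and LHCB4.1, a light-harvesting protein of photosystem II, 4306.8 against 5954.7. Without a filter on low values the list stood at the 6.04th percentile, and on probe sets without a shared-probe suffix at the 11.1th, so in both it no longer stood apart. The median was -0.47 in both, and what changed was the pool of random lists and, without suffixes, the number of members, which was 3. It was the only one of the 6 lists with at least 3 measured members to stand apart, where 0.3 lists would do so by construction. The 0.3 holds for genes drawn at random. Genes of one pathway may shift together between any 2 samples, and such lists would stand apart more often.

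**Figure D3:**
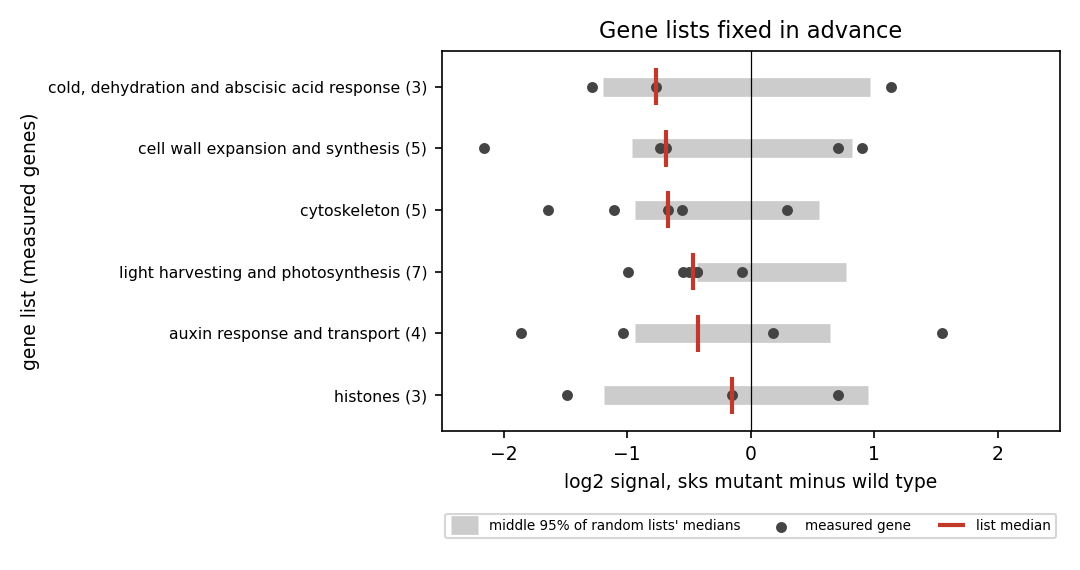
Log2 signal of the mutant minus that of the wild type for each measured gene (points) of the 6 lists with at least 3 measured members, with list medians as red lines. Grey bars span the middle 95% of the medians of matched random lists; the photosynthesis median of -0.47 lies outside its bar.

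The other 5 lists held members that differed in both directions or in few genes. In the cell wall list, 1 of 5 measured genes, the expansin EXPA8, was at least 2-fold lower (273.3 against 1221.4), while EXPA4 read 127.5 against 68.2, and the list median was -0.69 at the 7.48th percentile. In the cytoskeleton list, the actin gene ACT11 (192.2 against 599.9) and the tubulin gene TUA1 (35.3 against 76.2) were at least 2-fold lower, TUA1 only just, 3 further genes were within 2-fold, and the median was -0.67 at the 11.5th percentile. In the auxin list of 4 measured genes, the repressor gene IAA18 was 3.63-fold lower (22.7 against 82.5). WES1 (GH3.5) was 2.05-fold lower, only just past the limit. GH3.3, of the same family of auxin-conjugating enzymes, was 2.92-fold higher (70.0 against 24.0). That list's median was -0.43 at the 23.0th percentile, but -0.91 without the filter on low values and -1.03 without shared-probe suffixes. In the cold, dehydration and abscisic acid list of 3, the dehydrin gene COR47 was 2.43-fold lower (362.7 against 882.0), KIN2 2.19-fold higher (2191.4 against 998.9), and the dehydrin gene LTI30 read 58.8 against 100.2. All 3 probe sets carry a shared-probe suffix. The list median was -0.77 at the 6.97th percentile, but 0.18 without the filter on low values, so no direction is given for this list. Of 3 histone genes, the linker histone gene HIS1-3 was at least 2.39-fold lower and HIS4 and HTB2 were within 2-fold, with a median of -0.15 at the 45.8th percentile.

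For the remaining 17 lists, 2 or fewer members were measured and no list statement was possible. The 2 measured genes of the jasmonate and wound list were THI2.1 and THI2.2, which differed in opposite directions. The glutathione transferase gene GSTF3 read 340.8 against 106.4, more than 2-fold higher, on a probe set that can detect related family members. WRKY6 of the salicylate list read 61.4 against 55, UGT74B1 of the glucosinolate list 42.8 against 58.9, GI of the clock list 259.7 against 171.2, EIN3 of the ethylene list 1555.3 against 1687.4, and PRL of the cell cycle list 486.1 against 385.2. ICL was the only measured member of the seed list. No member was measured in the lists for root markers, meristem and floral regulators, epidermis and cuticle, heat shock, phenylpropanoids, gibberellin and brassinosteroid, nitrogen and sulphur assimilation, dark and sugar starvation, or cytosolic ribosomal proteins. In 7 of these 9 lists no member had a single-gene probe set named in the annotation used here, so the level of their transcripts is unknown rather than low. The heat shock and phenylpropanoid lists had named members, all below the signal limit. Differences in the make-up of the seedlings could therefore not be read from root, floral or epidermal markers.

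RNA and array quality measures differed in part between the samples. The ratio of the 3′ to the 5′ probe set was 4.14 in the mutant and 2.94 in the wild type for GAPDH, and 4.65 and 4.84 for ubiquitin. The 3′ GAPDH signal was 2730.2 in the mutant and 1117.2 in the wild type. The 25S ribosomal RNA control read 117.2 against 296.8. All 9 hybridisation spikes were brighter in the mutant, with a median ratio of 1.36 and a range of 1.12 to 1.85. Within the arrays, 80 genes had at least 2 measured probe sets. The log2 differences of one gene's probe sets had a pooled SD of 0.65. The median absolute difference between 2 probe sets of one gene was 0.33, over 101 pairs. THI2.1 raises the SD. Its log2 differences were 5.42 and 5.03 on 2 probe sets, whereas its _i_at probe set was lower in the mutant. Of 34 pairs in which at least 1 probe set differed 2-fold, 32 had the same direction. Pairs of probe sets were hybridised with the same RNA, can share probes and can read related transcripts, so this spread is no measure of replicate error.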

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

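Counts of probe sets at least 2-fold higher and lower were 335 and 510, and stayed within 1.5 times of these under median centring, quantile normalization, loess removal, the added offset and the blank-signal floor. They were 194 and 259 with the filter at the 75th percentile, 1008 and 1258 without a filter, 105 and 185 at 3-fold, 751 and 1048 at 1.5-fold, and 96 and 175 on single-gene probe sets without a shared-probe suffix, where the numbers tested or the limit differ by construction. With spike scaling, chosen after seeing the data as was the floor, they were 135 and 1092. In all 11 settings fewer probe sets were higher than lower. The photosynthesis median of -0.47 was -0.37 after median centring, -0.41 after quantile normalization, -0.57 after loess removal and -0.91 after spike scaling. It stayed negative in every setting, but stood apart neither without a filter nor without shared-probe suffixes. The median was -0.47 in both, so the change lay in the random lists and, without suffixes, in the 3 members left. The cold, dehydration and abscisic acid median of -0.77 was 0.18 without a filter, where 1 more, dim member joins. The auxin median of -0.43 was -0.91 without a filter, -1.03 without suffixes and -0.87 with spike scaling. Cell wall, cytoskeleton and histone medians stayed negative wherever at least 3 members remained. With 3 to 5 members in most lists the range of the members is wide, so lying within it says little. Fewer than 3 members remained in 2 of the 6 lists under the stricter filter and in 2 without suffixes. Of 54 named probe sets, the 36 that differed 2-fold kept their direction under the 6 settings tried on them. Among the others, spike scaling turned PRL from 0.34 to -0.11, IAA20 from 0.18 to -0.26 and WRKY6 from 0.16 to -0.28. Of the 36, WES1 (-1.03) passed below 2-fold under centring, quantile normalization, loess removal and the offset, TUA1 (-1.11) under quantile normalization and loess removal, and KIN2 (1.13) under spike scaling. THI2.1 (_s_at), AT4G02360 and AT2G39040 moved by more than 0.65 with the added offset, and these and AT2G19970 with the floor (to 3.22, 2.24, -2.28 and 3.05), as their dimmer signals were within the blank range. No replicate could be left out. No paired analysis was possible because each genotype had 1 array.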

Other observations

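The genes in the first 2 paragraphs were chosen after their values were seen. Several genes of carbon fixation and photorespiration had lower signals in the mutant. HPR, the peroxisomal hydroxypyruvate reductase of photorespiration, read 425.6 against 2232.1 (5.24-fold lower). PRK, the phosphoribulokinase of the Calvin cycle, read 470.4 against 1336.9, and SBPASE, the sedoheptulose bisphosphatase, 300.4 against 790.8. The photosystem II assembly factor gene PSB27 (919.7 against 2523) and the thioredoxin gene TRXF2 (904.5 against 2105.2) were 2.74-fold and 2.33-fold lower. The thylakoid ascorbate peroxidase gene TAPX was 2.66-fold and 2.39-fold lower on its 2 probe sets, whereas the stromal ascorbate peroxidase gene SAPX was 4.67-fold higher (83.6 against 17.9). STOMAGEN, which encodes a peptide that promotes stomata, read 45.2 against 143.9.

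Higher in the mutant beyond the genes named above were the pectin methylesterase gene ATPMEPCRB (PME41), 7.21-fold and 7.81-fold on its 2 probe sets, the calmodulin-like gene CML41 (55.8 against 7.1), and YLS5, 3.37-fold and 3.00-fold on its 2 probe sets. The wild-type signal of CML41 was within the blank range, below 11.1, so no fold is given for it. The glucosinolate transporter gene GTR1 read 244.6 against 72.6, and PORB, a protochlorophyllide reductase gene, 346.7 against 156.3. Unnamed here were 2408 measured probe sets without a single gene, of which 205 were at least 2-fold higher and 296 at least 2-fold lower. Among them 13267_at read 1.4 in the mutant and 913.4 in the wild type, at least 54.4-fold lower. Higher were 14832_at, at 205.1 against 2.1 (at least 18.5-fold), and 13197_r_at, at 203.2 against 3.3 (at least 18.3-fold). Their log2 differences of -9.35, 6.61 and 5.94 were larger than any in the same direction among measured probe sets of 1 gene, but their dimmer signals were within the blank range.

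In what follows, the spike-scaling test was chosen after the counts were seen. A hypothesis is that the pathway of carbon fixation and photorespiration was lower as a whole. A list of 30 textbook genes, written after HPR, PRK and SBPASE had been seen, had 6 measured members, of which 1 (RCA) is also in the photosynthesis list. All 6 were lower, 4 of them at least 2-fold, with a median of -1.45 at the 0.07th percentile of matched random lists. This percentile includes the genes that prompted the list and so decides nothing. The test set beforehand left out HPR, PRK and SBPASE. The median of the other 3 members was -0.97 at the 4.12th percentile, above the 2.5th percentile it had to lie below, so the list did not stand apart and met the outcome written for no change of the pathway. That outcome was set with too few members, as random lists of 3 vary widely, and 1 of the 3 is RCA, whose lower signal had also been seen. This leaves 2 members, AT1G11860 (286.6 against 910.9) and AT1G56190 (366.9 against 719.3, on a probe set with the _f_at suffix), too few for a list statement. The hypothesis stays open.

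More probe sets were lower than higher in the mutant, and the scaling of the arrays may account for this. Higher probe sets made up 39.6% of all 2-fold differences with the deposited scaling, 47.1% after median centring and 11.0% after scaling to the spikes. Median centring sets the median signals of the 2 arrays equal, which need not balance the directions. With it the median log2 difference of measured probe sets went from -0.08 to 0.01. Whether equal medians are the right scaling cannot be checked here, so the 47.1% does not settle the question. Spike scaling moved the balance further from even, but only as far as the spikes can be trusted, so a shift in scaling and an excess of lower transcripts cannot be told apart. What keeps it open is that neither the amount of spike nor the amount of cRNA on each array is known here.

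The large differences could come from noise of single probe sets, from variation between seedling samples, from the differences in RNA and array quality given above, or from the genotype. All pairs of probe sets of one gene agreed in direction in 32 of 34 cases, but 33 of them involve suffixes that mark shared probes, and genes with more than 2 probe sets give several linked pairs. The 2 that disagreed were both of THI2.1 and share a probe set. The share of agreeing pairs without such a suffix was 100%, from 1 pair, which decides nothing about the measurement noise of single probe sets. With 1 array per genotype, variation between seedling samples of one genotype, differences in RNA and array quality and an effect of sks cannot be told apart.

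A further hypothesis was that neighbouring genes differ together. A chromosome segment of other origin linked to the insertion might produce this within the segment. It could hold only few of the pairs, so a correlation over all chromosomes can neither show nor exclude such a segment. Across 1619 pairs of neighbouring measured genes the correlation of log2 differences was 0.0618, at the 98.8th percentile of 10000 shuffled gene orders, so neighbours were slightly more alike than in shuffled orders. Similar genes lying side by side are a candidate cause. Without neighbours within 20 kb the correlation was 0.0641 over 838 pairs, at the 95.2th percentile, and within 20 kb it was 0.0597 over 781 pairs. The value did not fall, but fewer pairs widen the shuffled range, and the cause stays open.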
